A study of Homo sapiens with 10 samples.

How the data were processed

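RNA from MCF10AT1 and DCIS.COM cells carrying a control or a CRYBB2 lentiviral vector was hybridized to 10 one-colour (Cy3) Agilent arrays, per the labels' protocols. There were 4 groups: MCF10AT1 control and MCF10AT1 CRYBB2 with 3 arrays each, and DCIS.COM control and DCIS.COM CRYBB2 with 2 arrays each. Groups, replicate numbers and batches were taken from the labels: batch 1 held 8 arrays and batch 2 the 2 arrays numbered 2.1. The authors read the scans with Agilent Feature Extraction, per the submitters' processing notes, in version 10.7.3.1, per the file headers. The unit of every value used is intensity, per the file headers: the processed signal was background subtracted and detrended within the array, with low values replaced by a surrogate. Probe coordinates are those of hg19, per the file headers. The values in the deposited table are intensity too: all 43404 values of every array equalled the processed signal of the scanner files within 1e-06, and their medians ran from 77.0 to 115.8, so they were neither quantile normalized nor batch corrected, although the submitters' processing notes name both steps. The tests start from the scanner files for this reason.

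From each scanner file, 43118 non-control spots were read. Spots that Feature Extraction called outliers were left out and the spots of a probe were averaged, which gave 34058 of 34127 probes a value: 33128 probes have 1 spot and 999 have 10, and 69 were left out because every spot was an outlier on an array. Probes were named by accession (25373), symbol (1160) or synonym (381) from the gene table, and 7144 kept the name in the file only. The log2 values were quantile normalized between arrays. Probes well above background on every array of at least 1 group were kept (23184), and the probe with the highest mean stood for its gene, which left 18677 genes: 15117 with a matched symbol and 3560 under a probe ID. Between 55.6% and 71.6% of the spots on an array were well above background and no spot was saturated.

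Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0): 1 linear model with the 4 groups and the batch as an additive term, moderated variances (residual df 5, prior df 2.5), two-sided tests, and the Benjamini-Hochberg adjusted p under 0.05 as the threshold. The 5 comparisons were the CRYBB2 effect in each line, its average over the lines, its difference between the lines (DCIS.COM minus MCF10AT1) and DCIS.COM against MCF10AT1 under the control vector. Position on the slide goes with the group and cannot be told apart from it. The 25 gene lists (519 genes, 515 on the array, 458 tested) were tested with camera at the preset correlation of 0.01, with camera at an estimated correlation and with fry, and the members of a list also by adjusting over the list alone. Lists, comparisons, tests and alternatives were chosen before the data were examined. The 1 exception among the fits is the fit with 2 and 2.1 averaged and the replicate block together, and for lists the omission of single arrays, which were chosen after seeing the data. The 25 lists are crystallins, G1/S and DNA replication, mitosis, nucleolus and ribosome biogenesis, EGF receptors and ligands, ERK feedback and immediate early genes, mesenchymal genes, epithelial junctions, basal and myoepithelial genes, luminal genes, stem and progenitor genes, interferon response, NF-kB cytokines, hypoxia and glycolysis, cholesterol synthesis, unfolded protein response, heat shock, p53 targets, NRF2 targets, keratinocyte differentiation, matrix and TGF-beta targets, and markers of fibroblasts, endothelium, blood cells and packaging cells.

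Genes were named by a fixed rule. For each comparison these were the 10 largest positive and 10 largest negative differences among genes past the threshold, well above background on every array of the brighter group and of 1 sign on every slide holding both groups. Where none passed, the 5 largest of each sign with an unadjusted p under 0.01 were named and said not to pass. Up to 4 members past the threshold were named per list, or else the 2 largest, and CRYBB2, CRYBB2P1 and NCL were always named. Further members that passed adjusted over the list alone, TRPM2, PAX8-AS1, the unnamed probes, the genes that moved in both lines and the families in the closing section were chosen after their values were seen. Probes annotated to chromosome Y are not named here.

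Arrays that share a replicate number share a slide. The deviations from the group means correlated at 0.441, 0.442 and 0.56 between the MCF10AT1 control and CRYBB2 arrays numbered 1, 2 and 2.1, and at 0.894 between the DCIS.COM arrays of 1 number, so within a line the numbers pair the samples, and a replicate block in place of the batch was run as an alternative. Across the lines arrays of 1 number correlated both ways, at 0.357 for MCF10AT1 control 1 with DCIS.COM control 1 and at -0.196 for MCF10AT1 CRYBB2 1 with DCIS.COM control 1. A block over both lines therefore rests on the shared slide. It fits 1 slide effect common to both lines, so the pairing within a line was not modelled on its own. Arrays 2 and 2.1 were counted as 1 sample for n, SD and bars, because their levels were far closer than those of other arrays, and a fit with them averaged was run beside each result. The labels do not say what the number 2.1 stands for.

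The other alternatives were scaling by the 75th percentile, normexp background correction with an offset of 50, no batch term, ComBat with the group in its model (as implemented here), no filter on dim probes, probes well above background on all arrays only, batch 1 only, only the arrays compared, the mean of a gene's probes, the deposited table without a batch term, an intensity trend in the variances, each array left out in turn, and the differences within each slide with no test. Where leaving out an array left a group with 1 array, that array was assumed to vary like the other groups. Bright genes, used to compare arrays, have a mean log2 level of at least 8 (10304 genes). Lists with fewer than 3 genes tested would have been left out. Splits of the arrays into other groups of the same sizes were fitted with the same model.

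The fits were tested on simulated data: known changes were added to 67 or 66 of the 18677 genes at each size. At a log2 change of 1 the tests found 34.3% in MCF10AT1, 7.46% in DCIS.COM and 20.9% between the lines, at 2 they found 75.8%, 59.7% and 72.7%, and at 4 they found 100%, 98.5% and 95.5%, with 0 wrong signs and 8, 5 and 7 unchanged genes called. A list shifted by 0.5 was called in each comparison, and 0, 0 and 1 other lists were called. The simulation modelled no correlation between genes, no pairing by slide and no near-duplicate arrays. In the data the estimated correlation within a list reached 0.931 for mitosis and was 0.54 for cholesterol synthesis. The shares found and the false calls therefore hold for the simulated data only. They do not show how often unchanged genes or lists are called on the real arrays. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.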

Results

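The arrays measured gene expression in 2 human breast epithelial cell lines, MCF10AT1 and DCIS.COM, each carrying a control lentiviral vector or a vector for CRYBB2, the gene of the lens protein beta-B2 crystallin. MCF10AT1 is a premalignant line with an activated HRAS gene, and DCIS.COM, of the same lineage, forms lesions in mice that resemble ductal carcinoma in situ. There were 10 arrays on 3 slides. Slide 1 held the 4 arrays numbered 1, slide 2 the 4 numbered 2, and slide 3 the 2 MCF10AT1 arrays numbered 2.1. Over 10304 bright genes the log2 levels of arrays 2 and 2.1 differed with an SD of 0.154 for the control and 0.156 for the CRYBB2 vector, against 0.343 to 0.618 for the other pairs of MCF10AT1 arrays within a group. Arrays 2 and 2.1 are therefore counted as 1 sample, and n is 2 in every group. The fit behind each SE and p-value below still took them as separate arrays, 3 per MCF10AT1 group, and a fit with them averaged was run beside it. Nothing in the labels says that the samples came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The spots well above background made up 55.6% on MCF10AT1 control 2 and 64.9% to 71.6% on the other arrays. The mean signal of negative control spots was 167 on MCF10AT1 control 1 and 38.5 to 48.6 on the others, and the number of arrays limits the precision of every difference below.

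The cell line was the main axis of the data: the first principal component held 68.6% of the variance and parted the lines. MCF10AT1 CRYBB2 1 stood apart on the next component, which held 10.8% of the variance: it lay at -27.8 and -74.6 on these 2 components. The other 5 MCF10AT1 arrays lay between -77.7 and -58.4 on the first and between -11.6 and 46.5 on the second. The second component also went with the vector in MCF10AT1. The control and CRYBB2 arrays lay at -11.6 and -74.6 on slide 1, 46.5 and -7.62 on slide 2, and 24.5 and -1.29 on slide 3.

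**Figure D1:**
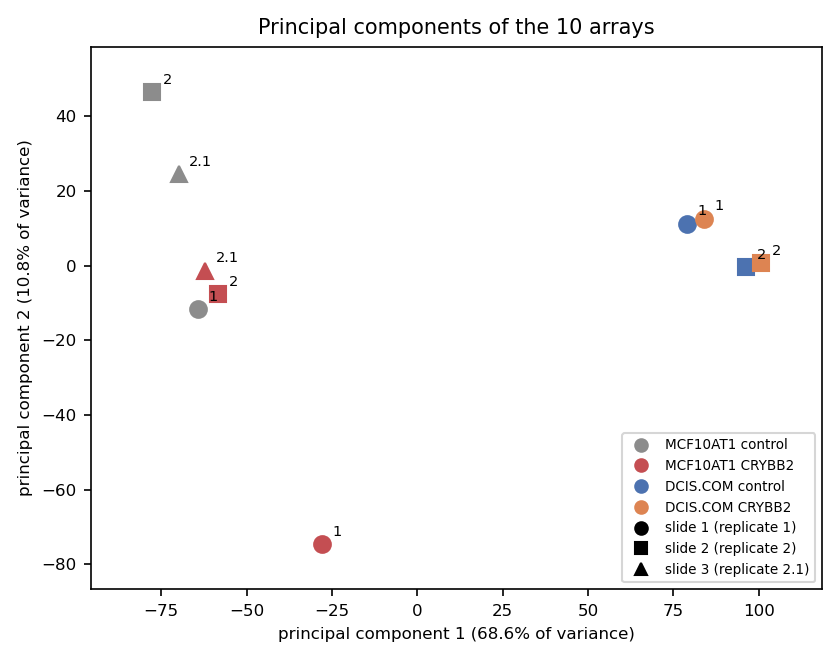
Principal components of the 10 arrays over the genes tested, coloured by group, with the slide as the marker. MCF10AT1 CRYBB2 1 lay apart from the other MCF10AT1 arrays.

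The targeted gene came first. The probe of CRYBB2 (chromosome 22, 25625428 to 25625487, hg19), which also matches transcripts of the pseudogene CRYBB2P1, read 8.31, 8.04 and 8.21 on the log2 scale on MCF10AT1 control 1, 2 and 2.1, and 8.88, 9.80 and 9.82 on MCF10AT1 CRYBB2 1, 2 and 2.1. It read 9.02 and 8.71 on the DCIS.COM controls and 9.62 and 9.38 on the DCIS.COM CRYBB2 arrays. As group means with their SD (n = 2) these were 8.22 ± 0.13 and 9.35 ± 0.66 in MCF10AT1 and 8.86 ± 0.22 and 9.50 ± 0.17 in DCIS.COM. CRYBB2 was 2.48-fold higher with its vector in MCF10AT1 (log2 difference 1.31, SE 0.26, adjusted p = 0.00348 over CRYBB2, CRYBB2P1 and NCL alone, higher on all 3 slides by 0.57, 1.76 and 1.61), although the adjusted p over all genes was 0.205. With arrays 2 and 2.1 averaged the difference was 1.13 (adjusted p = 0.0321 over the same 3 genes), and with the replicate block as well the adjusted p was 0.0593. In DCIS.COM the probe differed by 0.64 (SE 0.32, 1.56-fold, adjusted p = 0.243 over the 3 genes, higher on both slides by 0.60 and 0.67). This passed only without MCF10AT1 CRYBB2 replicate 1 (adjusted p = 0.0381 for the value of 0.64). Averaged over the lines CRYBB2 was 1.97-fold higher (0.98, SE 0.20, adjusted p = 0.00502 over the 3 genes). Its effect was not shown to differ between the lines (difference -0.67, SE 0.41, adjusted p = 0.42). CRYBB2P1 differed by 0.093 and 0.038 with the vector in MCF10AT1 and DCIS.COM, and NCL, the gene of nucleolin, by -0.060 and 0.081, none of which passed.

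**Figure D2:**
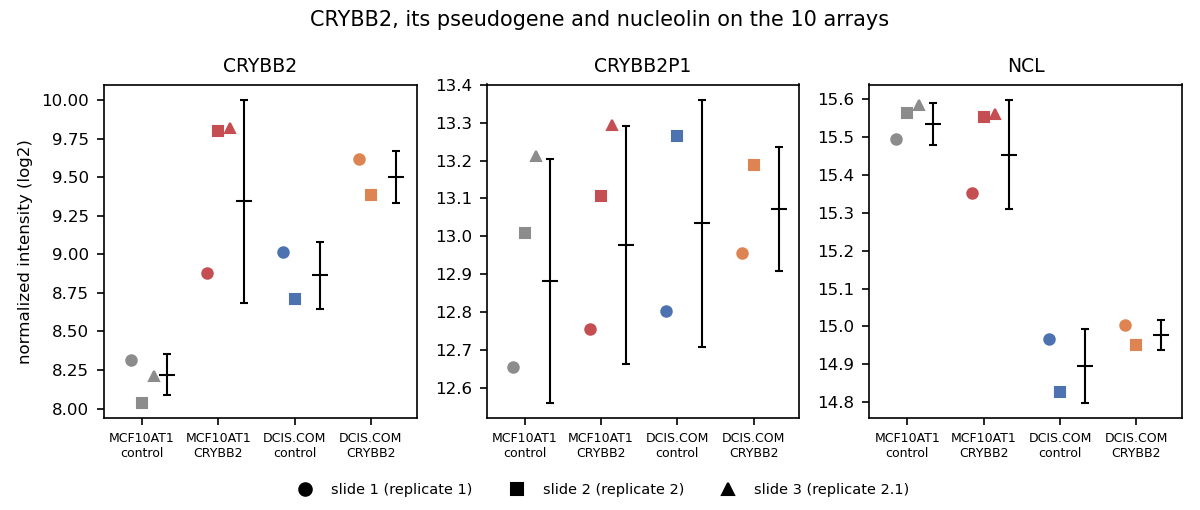
Levels of CRYBB2, CRYBB2P1 and NCL on each array by group, with the slide as the marker and the bar at the mean ± SD of replicates 1 and 2, arrays 2 and 2.1 averaged first.

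The comparison of the CRYBB2 vector with the control vector in MCF10AT1 asks what the vector changed in the premalignant line. Among genes that rose, CTLA4, an inhibitory receptor of T cells, was at least 3.46-fold higher (log2 difference 3.65, SE 0.30, adjusted p = 0.0117, n = 2 per group) and CAMP, which encodes the antimicrobial peptide cathelicidin, was 3.92-fold higher (1.97, SE 0.16, adjusted p = 0.0117). RDH16, a retinol dehydrogenase, was 2.74-fold higher (1.45, SE 0.16, adjusted p = 0.0437). Among genes that fell, GPC5, a cell-surface heparan sulfate proteoglycan, was at least 6.82-fold lower (-4.36, SE 0.26, adjusted p = 0.00211), and ABCA5, a lipid transporter of the ABC family, was 9.02-fold lower (-3.17, SE 0.19, adjusted p = 0.00211). ALDH1A3, which makes retinoic acid and marks mammary progenitors, was 2.85-fold lower (-1.51, SE 0.14, adjusted p = 0.0213). LCE2C, a late cornified envelope protein of skin, was at least 3.69-fold lower (-3.90, SE 0.40, adjusted p = 0.0289). The long noncoding RNA WDR11-DT was lower by far (-6.75, SE 0.53, adjusted p = 0.0109). It read 3.792, 1.507 and 1.535 on CRYBB2 1, 2 and 2.1 and stood well above background on 1 of these 3 arrays. The size of its difference therefore rests on background readings, and no lower bound is given. Each of these 8 genes moved in the same direction on all 3 slides, but the rule that named them required this, so it adds no support. The bound "at least" divides the bright group's mean over its replicates by the dim group's mean, in which each array takes the higher of the dim probe's own signal and the lowest signal among probes well above background.

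In all 13 genes or probes passed in MCF10AT1 (4 higher, 9 lower, 30.8% higher), among 1449 with an unadjusted p under 0.05. The others were TRPM2, a calcium-permeable channel (-2.03, SE 0.20, adjusted p = 0.0215), the antisense RNA PAX8-AS1 (at least 1.64-fold lower, -2.88, SE 0.31, adjusted p = 0.0363) and 3 probes with no gene name. Of these, A_33_P3398074 on chromosome 17, had the smallest adjusted p (0.000794, log2 difference -5.27, SE 0.24, at least 13.2-fold lower), and A_33_P3340189 (at least 1.45-fold, 2.63, SE 0.30, adjusted p = 0.0439) was higher. Of the 9 that fell, 5 were not well above background on any MCF10AT1 CRYBB2 array. With arrays 2 and 2.1 averaged 4 passed (CTLA4 at an adjusted p of 0.0197, GPC5 at 0.0178, ABCA5 at 0.0197 and A_33_P3398074 at 0.000916), while CAMP (adjusted p = 0.1), WDR11-DT (0.0639), RDH16 (0.373), LCE2C and ALDH1A3 (both 0.283) did not. With the replicate block 31 passed, 12 of them shared with the 13, all but A_33_P3340189 (0.0639). With only the MCF10AT1 arrays fitted 0 passed, so GPC5, ABCA5 and the others of the 13 all lost their call there. Leaving out either array numbered 2.1 takes both out of the test, because the batch term then fits the other exactly. With 1 array left out the count was 36 without MCF10AT1 control 1, 5 without MCF10AT1 CRYBB2 1, 6 without MCF10AT1 CRYBB2 2 and without either DCIS.COM CRYBB2 array, and 4 without either array numbered 2.1.

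GPC5 and ABCA5 kept their call without any 1 array (adjusted p at most 0.0284). CTLA4 lost its call without MCF10AT1 CRYBB2 1 (adjusted p = 0.0809), MCF10AT1 CRYBB2 2 (0.061) or either array numbered 2.1 (0.145). CAMP lost it without the same arrays (0.0799, 0.061 and 0.188), and WDR11-DT without either array numbered 2.1 (0.0998). ALDH1A3 lost it without MCF10AT1 CRYBB2 1 (0.0834), MCF10AT1 CRYBB2 2 (0.0937), MCF10AT1 control 2 (0.109), either DCIS.COM CRYBB2 array (0.061) or either array numbered 2.1 (0.271). LCE2C lost it without MCF10AT1 CRYBB2 1 (0.118) or 2 (0.0962), either DCIS.COM control (0.105), either DCIS.COM CRYBB2 array (0.0756) or either array numbered 2.1 (0.271). RDH16 lost it without every array but MCF10AT1 CRYBB2 1, with an adjusted p of up to 0.402.

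**Figure D3:**
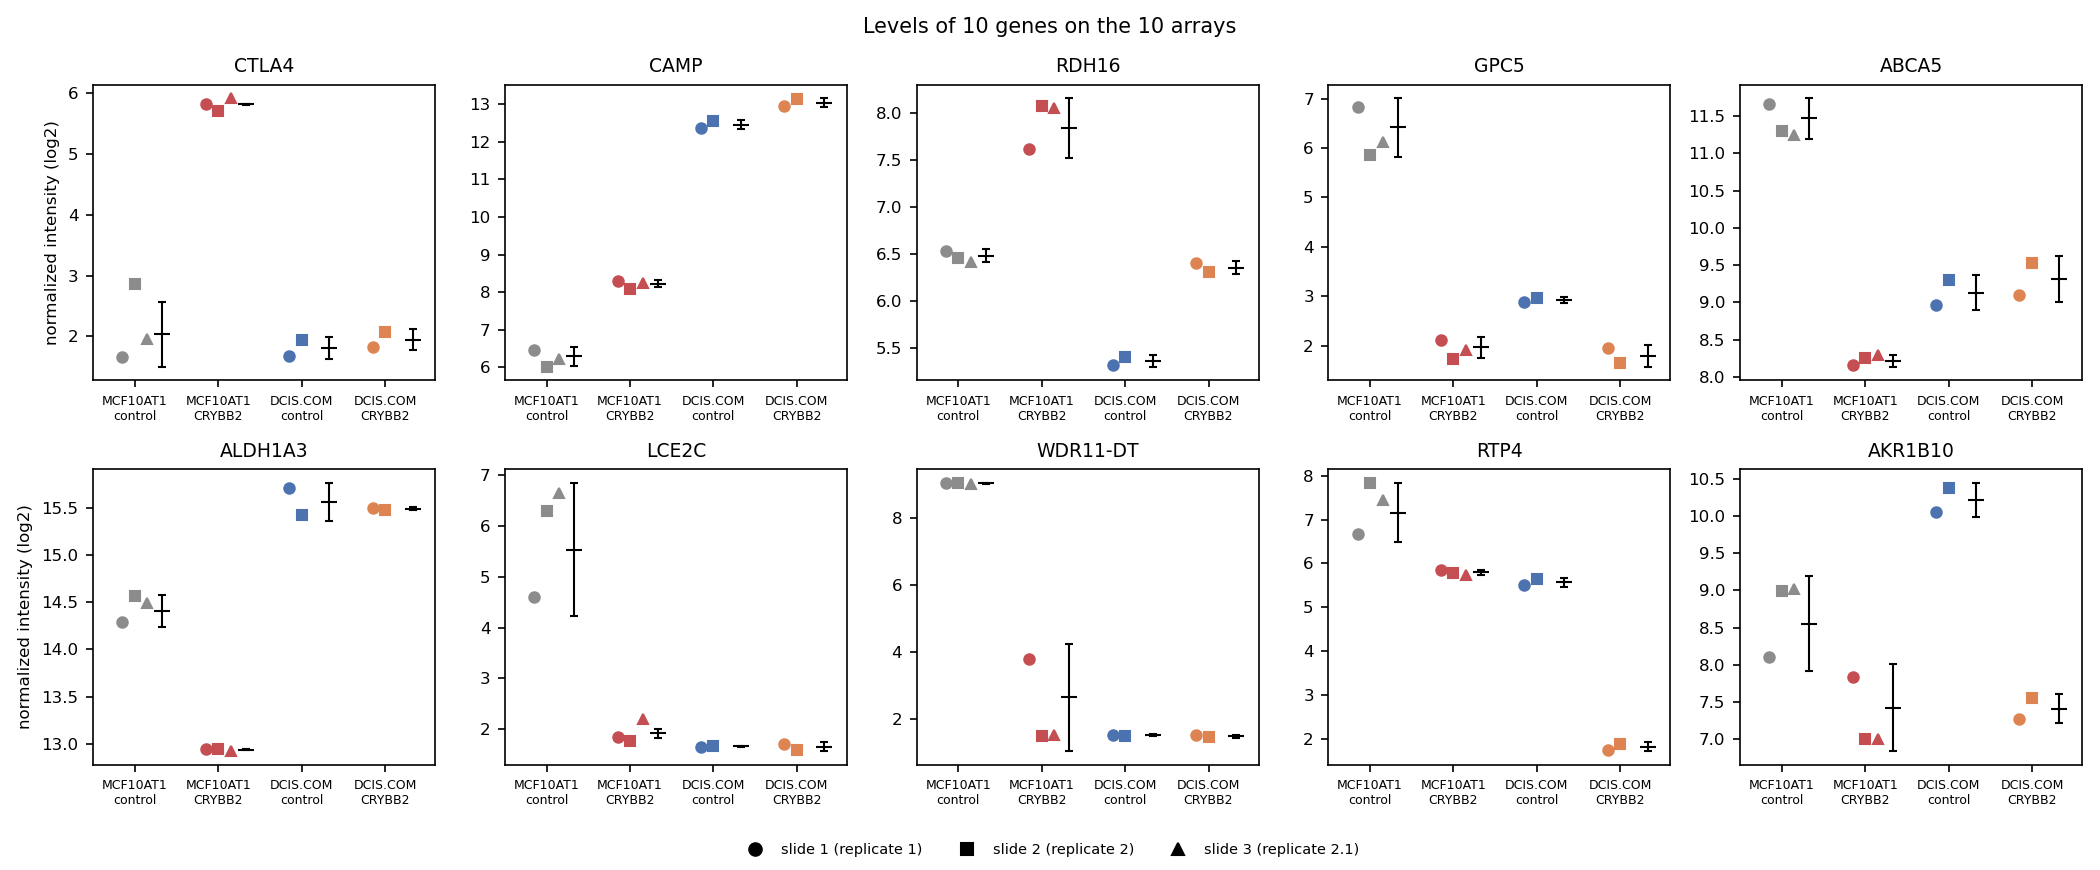
Levels of 10 genes of the CRYBB2 comparisons on each array by group, with the slide as the marker and the bar at the mean ± SD of replicates 1 and 2, arrays 2 and 2.1 averaged first.

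Of the 25 gene lists, 7 were shifted in MCF10AT1, all of them down. Keratinocyte differentiation genes, which build the cornified envelope, fell as a group (median of 23 genes -1.08, adjusted p = 1.91e-13, 2 of 23 positive), with IVL at -2.56, KLK10 at -2.20 and SBSN at -2.16. None of its members passed over all genes and 7 passed adjusted over the list alone, among them GRHL3, a transcription factor of epidermal barrier formation (-1.95), and S100A7 (-1.43). Cholesterol synthesis genes fell (median of 23 genes -0.69, adjusted p = 3.68e-11), with the enzymes HMGCS1 at -1.22 and MSMO1 at -1.19. Genes of epithelial junctions also fell (median of 21 genes -0.33, adjusted p = 3.51e-05), with the tight junction protein OCLN at -1.68 and the regulator OVOL1 at -1.40. NRF2 targets, genes of the oxidative stress response, fell by a smaller step (median -0.24, adjusted p = 0.00212), with AKR1B10 at -1.42 and HMOX1 at -0.68. NF-kB cytokines (median -0.35, adjusted p = 0.00333) held the interleukins IL1B at -2.27 and IL1A at -1.83. ERK feedback and immediate early genes (median -0.26, adjusted p = 0.0112) held DUSP5 at -1.01 and EGR3 at -0.96. G1/S and DNA replication genes (median -0.15, adjusted p = 0.0181) held E2F2 at -0.51 and CCND1 at -0.45. No list kept its call with an estimated correlation: keratinocyte differentiation had adjusted p = 0.377 with an estimated correlation, cholesterol synthesis 0.526, epithelial junctions 0.48, NRF2 targets 0.377, NF-kB cytokines and ERK genes 0.58, and G1/S genes 0.586.

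MCF10AT1 CRYBB2 1, the array that stood apart, moved with some of these groups. Within slides 1, 2 and 3 the median difference of the keratinocyte genes was -1.54, -0.998 and -0.865 and of the ERK genes -0.646, -0.0202 and -0.19. The median of the G1/S genes was 0.294, -0.365 and -0.342, and that of the NF-kB cytokines -0.0431, -0.602 and -0.593. Cholesterol synthesis (-0.591, -0.803 and -0.757), epithelial junctions (-0.323, -0.337 and -0.328) and NRF2 targets (-0.215, -0.27 and -0.179) were lower on every slide. The ERK list lost its call without MCF10AT1 control 1 (adjusted p = 0.198), MCF10AT1 CRYBB2 1 (0.076) or MCF10AT1 CRYBB2 2 (0.0517). The NF-kB list lost it without MCF10AT1 CRYBB2 2 (0.258), and the G1/S list without MCF10AT1 control 2 (0.123), MCF10AT1 CRYBB2 2 (0.352) or either array numbered 2.1 (0.253) and with 2 and 2.1 averaged (0.364). The other 4 lists kept their call without any 1 array.

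The other 18 lists did not pass in MCF10AT1. The unfolded protein response had a median of 0.25 (adjusted p = 0.0751, ASNS at 0.92 and ATF3 at -1.34) and passed with the replicate block (0.0428), but not with 2 and 2.1 averaged (0.366) or an estimated correlation (0.58). Its median was -0.254 on slide 1 and 0.30 and 0.27 on slides 2 and 3. The stem and progenitor list (adjusted p = 0.158) held ALDH1A3, the 1 of its 16 members that passed over all genes, and 2 members passed adjusted over the list alone, ALDH1A3 among them. Interferon response genes had a median of -0.20 (adjusted p = 0.112, OASL at -1.78, IFI27 at -1.51), and OAS1 passed adjusted over the list alone (-1.19, adjusted p = 0.0282). Crystallins (median 0.083, adjusted p = 0.204) held CRYBB2, which passed adjusted over the list alone (adjusted p = 0.0116), and CRYGN at 0.29. Among blood cell markers (adjusted p = 0.274) PTPRC at -1.02 and CD68 at -0.73 passed adjusted over the list alone. The tissue lists were basal and myoepithelial genes (adjusted p = 0.117, KRT6A at -1.62), luminal genes (0.233, FOXA1 at -1.28), mesenchymal genes (0.476, FN1 at -2.24 and CDH11 at 2.18), matrix and TGF-beta targets (0.158, LAMA4 at -1.32, which passed only with the replicate block at 0.0499), fibroblast markers (0.177, MFAP5 at -0.52), endothelial markers (0.232, VWF at 0.64) and packaging cell markers (0.929, NCAM1 at 0.37). The rest were hypoxia and glycolysis (0.204, ADM at -0.87), mitosis (0.274, ECT2 at -0.27), heat shock (0.382, HSPB1 at -0.47), nucleolus and ribosome biogenesis (0.633, NOP10 at -0.33), EGF receptors and ligands (0.929, ERBB4 at 0.92) and p53 targets (0.944, CDKN1A at -0.47). Median and test differed in sign for luminal genes (median 0.041, mean -0.073), packaging cell markers (0.049 and 0.062) and p53 targets (0.16 and 0.053), and for EGF receptors and ligands the median and mean did (-0.088 and 0.047). All 4 were tested as down.

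**Figure D4:**
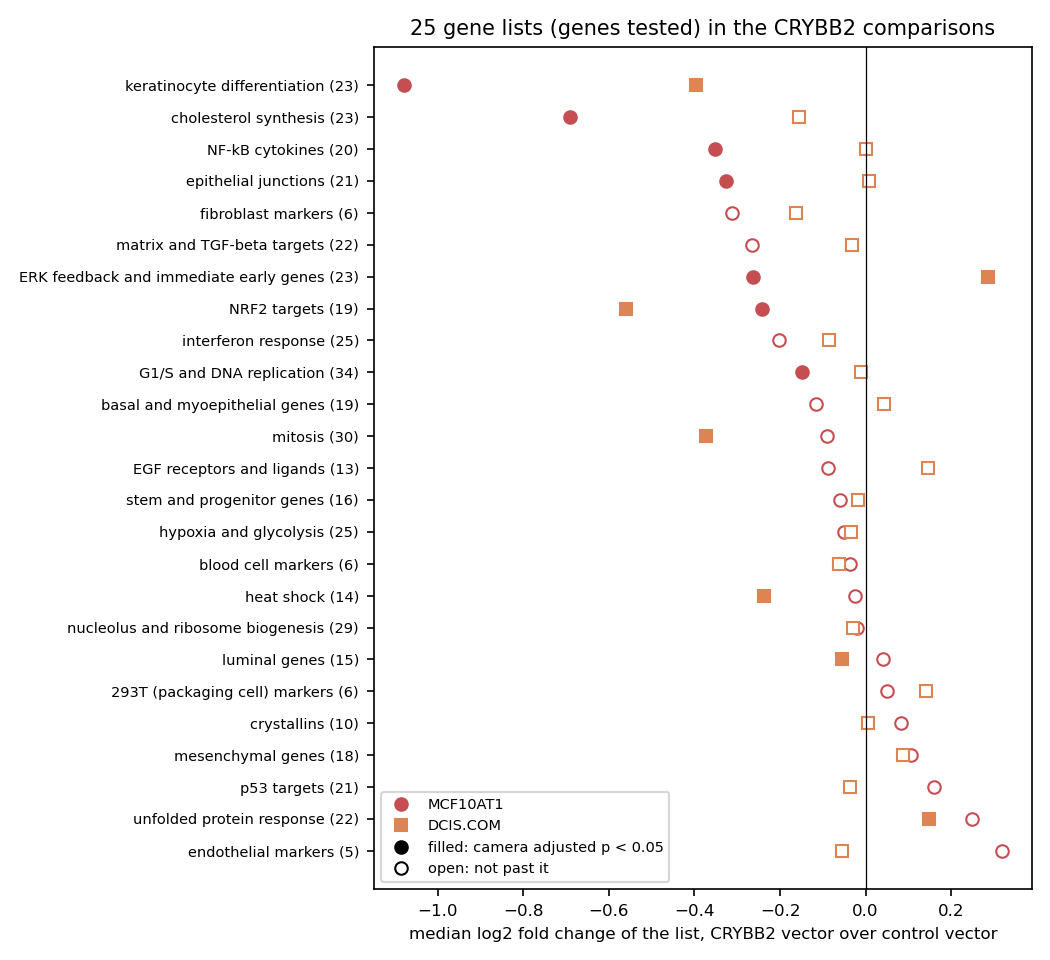
Median log2 difference of each of the 25 gene lists with the CRYBB2 vector, by cell line. Called lists are those with a camera adjusted p under 0.05 at the preset correlation.

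The same comparison in DCIS.COM asks what the CRYBB2 vector changed in the line that forms lesions in mice. No gene passed there by limma (smallest adjusted p = 0.111), with 234 at an unadjusted p under 0.05. That is a share below 0.05 of the 18677 genes tested, the mark for chance, and so no sign of an effect. Over the bright genes the 2 arrays of a slide differed with an SD of 0.233 and 0.245, against 0.547 and 0.525 between replicates of a group. The test counts this slide difference as spread, so 0 calls do not show that nothing changed. A fit with the slide pairs of this line alone was not run. The genes below are the most extreme differences among those of 1 sign on both slides, as the naming rule required, and none passes. NLGN4X, a synaptic adhesion protein, was at least 7.66-fold higher (3.05, SE 0.32, adjusted p = 0.111, n = 2 per group, 2.89 and 3.21 on the 2 slides), and ALDH1L1, an enzyme of folate metabolism, was 7.01-fold higher (2.81, SE 0.43, adjusted p = 0.525). CLEC4A, a lectin receptor of myeloid cells (2.22, SE 0.36), ARL10 (at least 1.41-fold, 2.15, SE 0.57) and the zinc finger protein ZFP69 (1.94, SE 0.35) had the next values. RTP4, an interferon-induced chaperone of receptors, was at least 4.21-fold lower (-3.75, SE 0.34, adjusted p = 0.111, lower on both slides), and the neighbouring aldo-keto reductases AKR1B15 and AKR1B10 were 7.32-fold (-2.87, SE 0.38, adjusted p = 0.292) and 7.03-fold lower (-2.81, SE 0.41, adjusted p = 0.454). ZNF475 (at least 1.52-fold lower, -2.49, SE 0.50) and the T cell costimulator ICOS (at least 2.11-fold lower, -2.44, SE 0.56) followed. With 1 array left out 1 gene passed without MCF10AT1 control 1, without MCF10AT1 control 2 or without DCIS.COM CRYBB2 2, and 0 passed without any other array.

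Of the 25 lists 7 were shifted in DCIS.COM, 5 down and 2 up, and no member of any list passed over all genes. NRF2 targets fell as a group (median of 19 genes -0.56, 3 of 19 positive, adjusted p = 6.00e-17, adjusted p = 0.0187 with an estimated correlation, fry adjusted p = 0.0381), by -0.547 on slide 1 and -0.497 on slide 2. AKR1B10 was the 1 member that passed adjusted over the list alone (adjusted p = 0.00323), and the exporter ABCC2 was at -1.64. This was the 1 of the 7 lists that kept its call with an estimated correlation and without any 1 array (adjusted p at most 5.61e-08). Mitosis genes (median of 30 genes -0.37, adjusted p = 3.54e-05, CENPF at -1.70, KIF20A at -0.87) and heat shock genes (median of 14 genes -0.24, adjusted p = 3.54e-05, HSPA8 at -0.69, HSPA1B at -0.50) had 0 positive members. ERK genes rose as a group (median of 23 genes 0.29, 21 positive, adjusted p = 7.71e-05), with EGR1 at 1.02 and EGR3 at 0.68. The unfolded protein response rose (median 0.15, adjusted p = 0.00753), with CHAC1 at 1.91 and DDIT3 at 1.19. Keratinocyte differentiation (median -0.40, adjusted p = 0.00146, KRT4 at -1.72, KLF4 at 1.16) and luminal genes (median -0.055, adjusted p = 0.0147, AGR2 at -1.16, MUC1 at -1.05) fell. These 6 lists lost their call with an estimated correlation: mitosis had adjusted p = 0.747 with an estimated correlation, keratinocyte differentiation 0.653, and heat shock, ERK, unfolded protein response and luminal genes 0.556.

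The slides differed in size for some of these groups. The mitosis median was -0.709 on slide 1 and -0.027 on slide 2, the ERK median 0.0875 and 0.511, and the unfolded protein response median 0.0398 and 0.274. Heat shock (-0.244 and -0.293), luminal genes (-0.167 and -0.106) and keratinocyte differentiation (-0.164 and -0.375) were lower on both slides. Leaving out 1 DCIS.COM array breaks a pair on a slide, which that fit does not model. A lost or turned call below therefore cannot be told apart from a difference between the slides. Without DCIS.COM CRYBB2 1 mitosis turned up (adjusted p = 3.43e-06) and the call was lost for ERK (0.263), the unfolded protein response (0.213) and luminal genes (0.426). Without DCIS.COM control 2 the call was lost for ERK (0.66, turned down), mitosis (0.526, turned up), the unfolded protein response (0.933, turned down) and luminal genes (0.424). Heat shock lost it without DCIS.COM control 1 (0.13) or DCIS.COM CRYBB2 2 (0.348), and keratinocyte differentiation without the same arrays (0.498 and 0.553).

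The other 18 lists did not pass in DCIS.COM. They were EGF receptors and ligands (adjusted p = 0.0617, AREG at 0.62), interferon response (0.196, IFI27 at -1.02), fibroblast markers (0.211, FAP at -0.88), crystallins (0.211), cholesterol synthesis (0.273, EBP at -0.70), packaging cell markers (0.418, GAL at 0.33), mesenchymal genes (0.598, MMP14 at -0.58), G1/S genes (0.598, CCNE2 at -0.38), hypoxia and glycolysis (0.598, CA9 at 0.65) and endothelial markers (0.666, ESAM at -0.13). Nucleolus (0.725, UTP20 at -0.47), matrix and TGF-beta targets (0.725, TGFB2 at -0.79), p53 targets (0.925, TP53INP1 at -0.60), NF-kB cytokines (0.925, SAA1 at -0.67), stem and progenitor genes (0.933, NANOG at -0.49), epithelial junctions (0.965, OVOL1 at 0.75), basal genes (0.965, OXTR at -0.42) and blood cell markers (0.965, CD68 at 0.57) had the highest adjusted p. Median, mean and test differed in sign for blood cell markers (median -0.063, mean 0.039, tested as up), epithelial junctions (0.0089, 0.020, down), NF-kB cytokines (0.00010, -0.023, down) and stem and progenitor genes (-0.017, 0.066, up).

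Averaged over both lines, the question is which genes moved with the CRYBB2 vector in either background. GPC5 passed (mean log2 difference -2.74, SE 0.21, adjusted p = 0.0168, -4.36 in MCF10AT1 and -1.13 in DCIS.COM), and so did RTP4 (-2.64, SE 0.22, adjusted p = 0.0213, -1.54 in MCF10AT1 and -3.75 in DCIS.COM). With the unnamed probe A_33_P3398074 (-2.72, adjusted p = 0.0168) these were the 3 that passed, all lower. An unadjusted p under 0.05 was found for 793 of the 18677 genes, a share below the 0.05 that is the mark for chance. GPC5 and A_33_P3398074 were not well above background on any DCIS.COM array, so for both the average rests on MCF10AT1. RTP4 was not above it on either DCIS.COM CRYBB2 array, so its value of -3.75 rests on background readings, and only the 4.21-fold given above is a lower bound. RTP4 did not pass with arrays 2 and 2.1 averaged (adjusted p = 0.0573) or with the replicate block (0.0667), and 2 genes passed in either fit. RTP4 also lost its call without MCF10AT1 CRYBB2 1 (0.0734) or 2 (0.131), DCIS.COM control 1 (0.219) or 2 (0.201), DCIS.COM CRYBB2 1 (0.147) or 2 (0.134), or either array numbered 2.1 (0.169). The count was 9 without MCF10AT1 control 1, 5 without MCF10AT1 CRYBB2 1, 0 without either DCIS.COM control and 1 without either DCIS.COM CRYBB2 array, MCF10AT1 CRYBB2 2 or either array numbered 2.1.

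No gene passed in both lines by limma at an adjusted p under 0.05. At an unadjusted p under 0.01, 15 genes moved in the same direction in both lines, against 0.882 if the lines were independent. Genes are not independent replicates of each other, however, and the lines shared slides. The 2 tests of a gene also share 1 estimate of its variance, which can raise the overlap with no shared effect. The 0.882 is therefore too low a mark for chance. The 4 higher ones were ALDH1L1 (1.36 in MCF10AT1 and 2.81 in DCIS.COM), RDH16 (1.45 and 0.99), ENKD1 (0.63 and 0.78) and ZNF300 (0.49 and 0.71). Among the 11 lower ones were FBXW10B (-2.09 and -2.45), BCAS1 (-1.45 and -2.36), the receptor GPR12 (-1.77 and -1.26), the chemokine CXCL17 (-1.13 and -1.38), C9orf152 (-1.07 and -1.04) and PLAAT2 (-0.83 and -1.13), beside GPC5, RTP4 and AKR1B1, AKR1B10 and AKR1B15. Some of these were dim: GPC5 was not well above background on any DCIS.COM array, RTP4, GPR12 and FBXW10B not on either DCIS.COM CRYBB2 array, and ZNF300 not on either DCIS.COM control. Of the 13 that passed in MCF10AT1, 10 had the same sign in DCIS.COM, although 4 of the 9 that fell were not well above background on any DCIS.COM array. The correlation of the effects of all genes was 0.13. Replicates within a line were not close either: over the bright genes the MCF10AT1 effects on slides 1 and 2 correlated at 0.321 and the DCIS.COM effects at 0.465. Between the lines the effects correlated at 0.323 on slide 2 and at -0.0298 on slide 1. The 0.13 therefore does not by itself show that the lines differ. Of the 25 lists 11 were shifted in the average. NRF2 targets fell in the average (median -0.38, adjusted p = 1.21e-11, adjusted p = 0.0471 with an estimated correlation, fry adjusted p = 0.0158), and 7 of its 19 members passed adjusted over the list alone. The other 10 lost their call, with an adjusted p of at least 0.304 with an estimated correlation. Of them, G1/S genes (adjusted p = 0.0276), luminal genes (0.0322) and interferon response genes (0.0344) did not pass with arrays 2 and 2.1 averaged (0.182, 0.102 and 0.174). With the replicate block the interferon list did not pass (0.0617) and fibroblast markers did (0.0472, against 0.0643), but not with 2 and 2.1 averaged (0.0704) or an estimated correlation (0.539).

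The difference of the CRYBB2 effect between the lines was tested as an interaction. An unadjusted p under 0.05 was found for 516 of the 18677 genes, a share below the 0.05 that is the mark for chance. Only A_33_P3398074 passed (5.10, SE 0.38, adjusted p = 0.0293). It did not pass with the replicate block (0.138) nor without DCIS.COM control 1, DCIS.COM control 2 or DCIS.COM CRYBB2 1, each of which left a count of 0. Without MCF10AT1 CRYBB2 1, MCF10AT1 control 2 or DCIS.COM CRYBB2 2 another gene passed in its place. The probe was not well above background on any DCIS.COM array. The named genes that follow did not pass. ABCA5 differed by 3.35 (SE 0.30, adjusted p = 0.0566), with mean levels of 11.47 and 8.21 in MCF10AT1 and 9.13 and 9.31 in DCIS.COM for the control and CRYBB2 vectors. WDR11-DT differed by 6.72 (SE 0.84, adjusted p = 0.249), PAX8-AS1 by 3.63 (0.249), LCE2C by 3.90 (0.534) and SRGN, a proteoglycan of secretory granules, by 3.79 (0.719). In the other direction CTLA4 differed by -3.52 (SE 0.48, adjusted p = 0.249), ICOS by -3.75 (0.719), and CYP4X1 (-2.99), WFDC2 (-2.67) and MCF2L-AS1 (-2.60) followed. WDR11-DT, LCE2C, SRGN and CTLA4 were not well above background on any DCIS.COM array, so their differences restate the effect in MCF10AT1. Within their own lists, ALDH1A3 (1.44, adjusted p = 0.00404) and CD68 (1.30, adjusted p = 0.0446) passed adjusted over the list alone.

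The comparison of DCIS.COM with MCF10AT1 under the control vector asks how the lines differ without CRYBB2. S100B, a calcium-binding protein, was at least 1201-fold higher in DCIS.COM (log2 difference 12.60, SE 0.52, adjusted p = 1.24e-05, n = 2 per group). Others higher in DCIS.COM were CCND2, a D-type cyclin (at least 113-fold, 9.32, SE 0.20, adjusted p = 1.18e-06), ACTG2, a smooth muscle actin (at least 184-fold, 9.32, SE 0.58), CHI3L1, a secreted chitinase-like protein (at least 211-fold, 9.52, SE 1.03), and BST2, the interferon-induced protein tetherin (8.94, SE 0.58). MT1M, a metallothionein that binds zinc and copper, was at least 3546-fold lower (-13.54, SE 0.24, adjusted p = 4.09e-07), and the kallikrein proteases KLK7 (at least 3709-fold lower, -13.05, SE 0.56) and KLK8 (389-fold lower, -8.60, SE 0.26) and the matrix proteoglycan DCN (at least 367-fold lower, -10.34, SE 0.35) were also lower. PI15 (9.16, at least 254-fold), BPIFB1 (8.68), TREM2, a receptor of myeloid cells (8.47), SCRG1 (8.47) and the tumour suppressor LZTS1 (8.11, at least 161-fold) completed the 10 largest positive differences. PLAC8 (-10.47, at least 751-fold), MYADM (-9.60, at least 227-fold), COXFA4L3 (at least 303-fold lower), the guanine deaminase GDA (-8.79, at least 154-fold), VSTM2L (-8.13, at least 83.9-fold) and BTBD16 (-7.95) completed the 10 largest negative ones. The rule that named these 20 required the same sign on both slides that hold the 2 groups. Each of the 20 kept its call without any 1 array.

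In all 3611 of 18677 genes passed, 2034 higher and 1577 lower in DCIS.COM (56.3% higher), and 2517 of them differed by at least 2-fold. With arrays 2 and 2.1 averaged 2607 passed and with the replicate block 4874. The count was 1615 without DCIS.COM control 2, 2287 without DCIS.COM control 1, 2361 without MCF10AT1 control 1, 2085 without MCF10AT1 control 2 and 2394 without either array numbered 2.1. Of the 91 genes named for this comparison, 35 lost their call without at least 1 array: 28 without DCIS.COM control 2, 17 without DCIS.COM control 1, 22 and 21 without MCF10AT1 control 1 and 2, 16 without either array numbered 2.1, 8 without MCF10AT1 CRYBB2 2 and 2 without either DCIS.COM CRYBB2 array. NCL was 1.54-fold lower in DCIS.COM (-0.62, SE 0.15, adjusted p = 0.0262, lower on both slides). Over all genes it did not pass with arrays 2 and 2.1 averaged (0.0723). Over CRYBB2, CRYBB2P1 and NCL alone NCL passed with all arrays (0.0109), with 2 and 2.1 averaged (0.0377) and with the replicate block (0.00715). CRYBB2 (0.76, SE 0.30, adjusted p = 0.127 over all genes and 0.0568 over the 3) and CRYBB2P1 (0.20) did not pass.

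Of the 25 lists 6 were shifted between the lines. Keratinocyte differentiation genes were lower in DCIS.COM (median of 23 genes -2.07, adjusted p = 0.000581), with 2 members higher and 11 lower, among them KLK7 and the serpins SERPINB3 (-6.14) and SERPINB4 (-5.59), and 17 passed adjusted over the list alone. NF-kB cytokines were lower (median of 20 genes -1.96, adjusted p = 0.00185), with 9 lower, such as the acute phase protein SAA1 (-5.14) and the inhibitor of apoptosis BIRC3 (-4.52), and 2 higher, among them the adhesion protein ICAM1 (4.54). Nucleolus and ribosome biogenesis genes were lower (median of 29 genes -0.47, adjusted p = 0.000581), with 5 lower and 0 higher, such as NOP58 (-0.74), NOP56 (-0.71), GNL3 (-0.65) and NCL, none of which passed over all genes with arrays 2 and 2.1 averaged (0.103, 0.0893, 0.0836 and 0.0723). The unfolded protein response was higher (median of 22 genes 0.73, adjusted p = 0.0115), with 5 higher and 0 lower, such as the endoplasmic reticulum proteins PDIA6 (1.62) and CALR (0.93, or adjusted p = 0.0812 with 2 and 2.1 averaged). Hypoxia and glycolysis genes were higher (median of 25 genes 0.71, adjusted p = 0.0174), with 7 higher and 0 lower, such as the glycolytic enzymes ENO2 (2.67), HK2 (1.59) and GAPDH (1.06). EGF receptors and ligands were higher (median of 13 genes 0.90, adjusted p = 0.0205), with 5 higher and 0 lower, such as the ligands NRG2 (4.24) and EREG (3.64) and the receptor ERBB4 (2.68, at least 1.61-fold). None of the 6 kept its call with an estimated correlation: keratinocyte, nucleolus, unfolded protein response and EGF lists had adjusted p = 0.614 with an estimated correlation, and the NF-kB and hypoxia lists 0.628. The EGF list lost its call without DCIS.COM control 1 (adjusted p = 0.165), and so did the unfolded protein response (0.21).

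The other lists did not pass as groups, but many of their members did. Mesenchymal genes (adjusted p = 0.486, 6 higher and 1 lower of 18) held SPARC (6.84), ITGB3 (6.92), CDH11 (6.04) and MMP2 (3.61, at least 4.50-fold), all higher. Basal and myoepithelial genes (0.849, 5 higher and 4 lower of 19) held MYLK (8.09) and NGFR (7.44) and, lower, the keratins KRT6A (-5.86) and KRT5 (-2.53). Luminal genes (0.113, 4 higher and 1 lower of 15) held the transcription factor SPDEF (3.26), AGR2 (3.14) and the mucin MUC1 (-2.99). Stem and progenitor genes (0.886, 5 higher and 2 lower of 16) held NANOG (2.74), PROCR (-1.89) and ALDH1A3 (1.12). Interferon response genes (0.269, 6 higher and 1 lower of 25) held BST2, OAS2 (2.63) and IFI44L (-2.51). ERK genes (0.287, 7 higher and 1 lower of 23) held SPRY2 (1.81), SPRY1 (2.49) and DUSP1 (-3.08). NRF2 targets (0.092, 6 higher and 2 lower of 19) held NQO1 (2.55), AKR1C1 (2.09) and ABCC3 (1.89). Matrix and TGF-beta targets (0.092, 2 higher and 6 lower of 22) held TGFBI (-7.30) and COL7A1 (-2.84), and fibroblast markers (0.092, 1 higher and 4 lower of 6) held DCN, FAP (-4.72) and FBLN1 (2.60).

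Fewer members passed in the remaining lists. These were p53 targets (adjusted p = 0.092, or 0.0281 with the replicate block but 0.0773 with 2 and 2.1 averaged and 0.687 with an estimated correlation, PLK3 at -1.41 and AEN at -1.04), heat shock (0.092, HSPB1 at -1.72 and CRYAB at -1.49), crystallins (0.389, CRYAB and CRYBA2 at -1.48) and blood cell markers (0.307, CD14 at -2.67 and PTPRC at -1.98). Also among them were G1/S genes (0.319, CCND2 higher, CCND3 at -1.77 and CCNE1 at -0.90), epithelial junctions (0.727, CLDN3 at 4.81, JUP at -1.16 and DSP at -1.11), endothelial markers (0.849, PECAM1 at 2.16), packaging cell markers (0.319, NCAM1 at 4.71) and cholesterol synthesis (0.727, SC5D at -0.76). With arrays 2 and 2.1 averaged AEN (adjusted p = 0.079), CCNE1 (0.0586), JUP (0.0604), SC5D (0.0831) and the keratin KRT5 (0.052) did not pass. No mitosis gene passed by limma (adjusted p = 0.113 for the list, CENPE at -1.21 and CENPF at 1.20), and 0 passed adjusted over the list alone. CENPE passed with the replicate block (0.0287). Median, mean and test differed in sign for basal genes (median -0.40, mean 0.27, tested as up), endothelial markers (-0.11, 0.18, up), epithelial junctions (-0.23, 0.029, down) and G1/S genes (-0.19, 0.083, down).

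**Figure D5:**
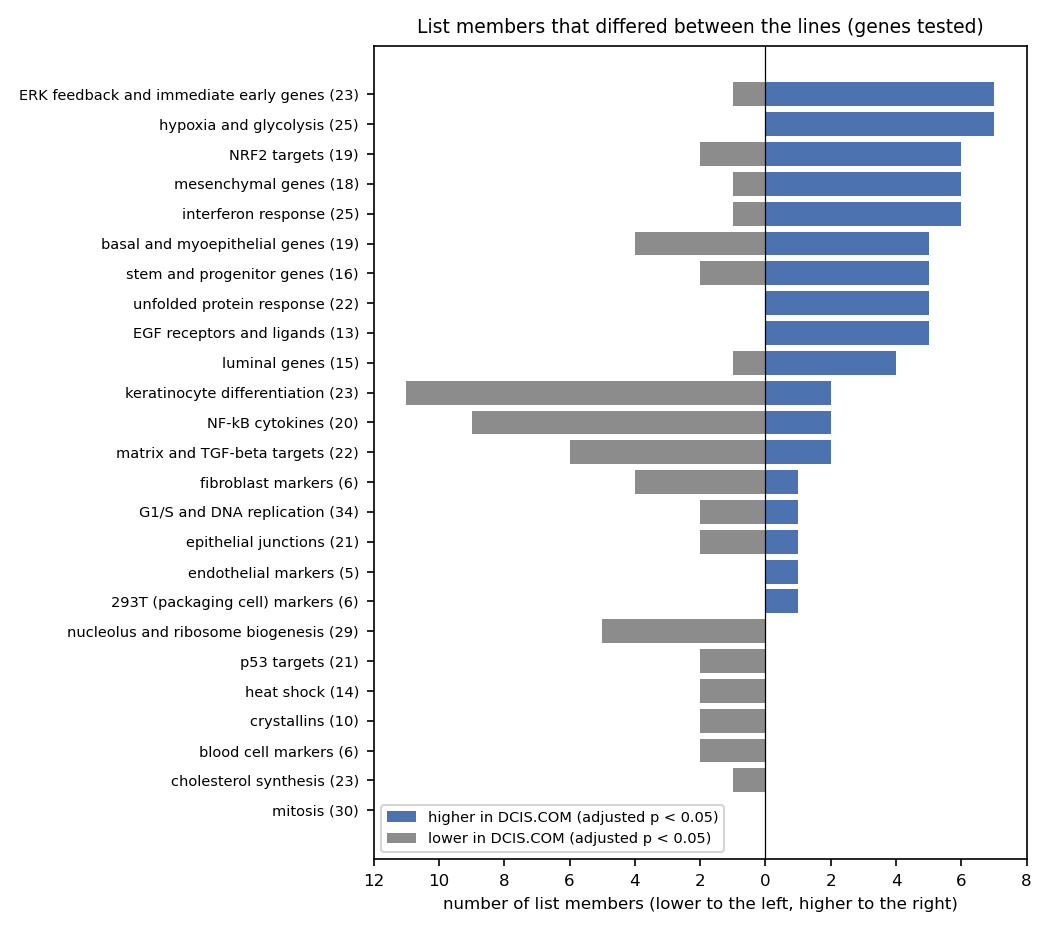
Members of each gene list that were higher or lower in DCIS.COM than in MCF10AT1 under the control vector at an adjusted p under 0.05. The number of genes tested stands beside each list.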

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

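The other splits for the 7 gene lists and for the average over the lines were chosen beforehand, and all other tests of explanations in this part were chosen after the results were seen. The 7 results that follow came up because the effect of the CRYBB2 vector differed between the lines by the test of the difference itself (DCIS.COM minus MCF10AT1, log2). The probe A_33_P3398074 differed by 5.10 (adjusted p = 0.0293), not with the replicate block (0.138), and no longer without DCIS.COM control 1, DCIS.COM control 2 or DCIS.COM CRYBB2 1, each of which left 0 genes, nor without MCF10AT1 CRYBB2 1, MCF10AT1 control 2 or DCIS.COM CRYBB2 2, where another gene passed. It was not well above background on any DCIS.COM array. Cholesterol synthesis had a median difference of 0.685 (adjusted p = 3.07e-06, adjusted p = 0.684 with an estimated correlation, 21 of 23 genes positive) and kept its call without any 1 array. Keratinocyte differentiation had 0.872 (adjusted p = 9.28e-06, adjusted p = 0.65 with an estimated correlation, 19 of 23 positive) and kept its call too. The ERK genes had 0.515 (adjusted p = 4.26e-06, adjusted p = 0.65 with an estimated correlation, 21 of 23 positive) and lost the call without DCIS.COM control 2 (0.231). Epithelial junctions had 0.284 (adjusted p = 0.000507, adjusted p = 0.65 with an estimated correlation, 17 of 21 positive) and lost it without DCIS.COM CRYBB2 1 (0.125) or DCIS.COM control 2 (0.134). NRF2 targets had -0.249 (adjusted p = 0.0117, adjusted p = 0.65 with an estimated correlation, 5 of 19 positive) and lost it without MCF10AT1 control 1 (0.197), DCIS.COM control 1 (0.0521), MCF10AT1 CRYBB2 2 (0.124) or DCIS.COM CRYBB2 2 (0.0623). NF-kB cytokines had 0.339 (adjusted p = 0.0199, adjusted p = 0.737 with an estimated correlation, 12 of 20 positive), and lost the call with 2 and 2.1 averaged (0.0773) and without MCF10AT1 control 1 (0.0762), DCIS.COM CRYBB2 1 (0.943), MCF10AT1 CRYBB2 2 (0.342), DCIS.COM control 2 (0.913) or either array numbered 2.1 (0.0634). The fry adjusted p was 0.956 for each of these 6 lists.

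The 13 genes and probes that passed in MCF10AT1, GPC5 and ABCA5 among them, and the 3 that passed in the average over the lines were set against other splits of the arrays. MCF10AT1 control 2, with the fewest spots well above background (55.6%), was argued against as the source of most of the 13: without it 9 were called, all of them among the 13. For MCF10AT1 control 1, with the highest signal on negative control spots (167), the same test cannot decide. Without it 36 were called, 11 of the 13 among them, but the control group then held only arrays 2 and 2.1. These count as 1 sample and vary as near duplicates, so the calls kept do not argue against MCF10AT1 control 1. The 4 not kept without MCF10AT1 control 2 stay open too. The 10 splits of the 6 MCF10AT1 arrays are too few for a share under 0.05. The real count was 13 and 3 of the 10 called as many. The highest other was 571, with control 1, CRYBB2 1 and CRYBB2 2 on 1 side. Both arrays numbered 2.1 were then on the other side, where the batch term took them up, so control 2 stood alone. Likewise CRYBB2 1 stood alone in the split that called 113. These counts are not comparable with the real one. The other splits with 1 array numbered 2.1 on each side, as in the real split, called 0 probes, with the limit given below. The 3 other splits that part all 3 pairs called 0 probes, which says little. Except for the split with control 1, CRYBB2 2 and CRYBB2 2.1 on 1 side, they set arrays 2 and 2.1 of a group on opposite sides. Any vector difference then counts as spread within the groups. Chance was not excluded for the average, where 18 of 60 splits called as many as the real 3, and the blocked count was 2. The highest other was 3197, with DCIS.COM parted by slide and both arrays numbered 2.1 again on 1 side. Among splits with 1 array numbered 2.1 on each side the highest other was 1020. There DCIS.COM was parted by slide too, which points to a structure of the samples. Among the 16 splits that part all 5 pairs the highest other count was 1, but those with MCF10AT1 control 2 and 2.1 on opposite sides have the same limit. An effect of the vector on these genes stays open, as a biological explanation that the splits cannot settle.

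The 7 lists shifted down in MCF10AT1, keratinocyte differentiation and cholesterol synthesis first, were tested in the same way, although none passed with an estimated correlation (adjusted p = 0.377 to 0.586) and 0 lists did with fry. The 10 splits are too few for a share under 0.05: the real split called 7 lists, the highest other 8, and 7 of the 10 splits called at least as many. The highest other was 8 also among splits with 1 array numbered 2.1 on each side. If the shift came from MCF10AT1 CRYBB2 1 alone it should be missing on slide 2, but 5 of the 7 lists had the same sign and at least 50% of the slide 1 median there, all but the ERK genes (-0.646 and -0.0202) and the G1/S genes (0.294 and -0.365). For the 5 lists the slide 2 values therefore argue against that array as the only source of the shift. The G1/S genes went the other way on slide 1, which holds that array, and this argues against it as the source of their fall. For the ERK genes its share cannot be told apart from an effect of the vector. Slides 2 and 3 count as 1 sample, so an effect of the vector stays open as the biological explanation for all 7.

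MCF10AT1 CRYBB2 1 stood apart from the other MCF10AT1 arrays, with higher levels of NGFR (9.73 against 6.15 on CRYBB2 2 and 2.1), NTRK2 (9.97 against 7.08) and SCRG1 (9.50 against 6.93), all high in DCIS.COM. DCIS.COM RNA mixed into the sample was argued against: the 74 genes far higher in DCIS.COM implied a median share of 0.542% (quartiles -0.0185% and 4.0%), and 22 of them were not raised on this array. The 10 of them brightest in DCIS.COM implied 0.675% (upper quartile 0.85%), while NGFR would need 6.73%, NTRK2 8.19% and SCRG1 6.11%. S100B, at 14.29 in DCIS.COM, read 2.73 on this array. Low signal was argued against as well, since 70.0% of its spots were well above background, within the range of 55.6% to 71.6% of the other arrays. A difference in the state or culture of these cells was not tested and stays open.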

How the results depend on the processing

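The fit with 2 and 2.1 averaged and the replicate block together, and for the lists the omission of single arrays, were chosen after seeing the data. Leaving out either array numbered 2.1 is the same fit as batch 1 only, so these are not separate alternatives. The call of CRYBB2 in MCF10AT1 kept its direction in every fit, and of 216 single genes followed over all settings 100 were called. Of these, 46 lost their call under at least 1 alternative and none reversed. The other 54 kept it under each alternative that tested them, but 27 of them were too dim to be tested above background on all arrays. Over all values, 5029 stayed on their side of the threshold, 306 were weaker, 32 stronger and 196 moved. Where a value changed, the cause was not tested. The deposited table, fitted without a batch term, moved the median of all genes from -0.041 to 0.102 in the difference between the lines, and the share of higher calls in MCF10AT1 from 30.8% to 8.82%. With only probes above background on all arrays 60 of the 100 called genes were tested and 59 passed, and the other 40 were not tested there. For the slide alternative only differences and no counts were had, and the fit of only the groups compared equals the fit of all arrays for the average and the difference, so it was not run there.

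The count in MCF10AT1 (13) was 27 with no batch term, 172 with ComBat, 31 with the replicate block, 3 above background on all arrays, 4 with 2 and 2.1 averaged, 3 with the block as well, 4 (0 higher) in batch 1 only, 34 from the deposited table and 0 from only the groups compared, where limma had fewer samples and the full fit had 1449 at an unadjusted p under 0.05. With 1 array left out it ran from 4 to 36: 36 without MCF10AT1 control 1, 5 without CRYBB2 1, 6 without CRYBB2 2, 4 without either array numbered 2.1, and 6 without either DCIS.COM CRYBB2 array. The count in DCIS.COM (0 by limma, 234 at an unadjusted p under 0.05) was 2 with normexp, 3 with no batch term, 6 with ComBat, 1 from the deposited table and 0 to 1 with 1 array left out (1 without MCF10AT1 control 1 or 2 or DCIS.COM CRYBB2 2).

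The count averaged over the lines (3) was 5 with the 75th percentile, 12 with no batch term, 46 with ComBat, 0 with no brightness filter (27418 genes tested), 3 above background on all arrays (none of them shared), 1 in batch 1 only, 7 from the deposited table, 5 with a trend and 1 with 2 and 2.1 averaged and the block. With 1 array left out it ran from 0 to 9: 9 without MCF10AT1 control 1, 5 without MCF10AT1 CRYBB2 1, 0 without either DCIS.COM control, and 1 without MCF10AT1 CRYBB2 2, either array numbered 2.1 or either DCIS.COM CRYBB2 array. The count for the difference between the lines (1) was 2 with the 75th percentile, no batch term, batch 1 only or a trend, 3 with normexp or the deposited table, 10 with ComBat, 1 above background on all arrays (another gene), and 0 with the replicate block, with no brightness filter or with 2 and 2.1 averaged and the block. It ran from 0 (without DCIS.COM control 1 or 2 or CRYBB2 1) to 2 (without MCF10AT1 control 1 or either array numbered 2.1).

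The count between the lines (3611) was 6116 with ComBat, 2394 in batch 1 only and 1803 from only the groups compared, and ran from 1615 to 4458 with 1 array left out: 1615 without DCIS.COM control 2, 2287 without DCIS.COM control 1, 2361 and 2085 without MCF10AT1 control 1 and 2, and 2394 without either array numbered 2.1. CRYBB2 in MCF10AT1 was 1.13 with 2 and 2.1 averaged and the block (adjusted p = 0.0593 over 3 genes) and 0.57, 1.76 and 1.61 within slides 1, 2 and 3. In DCIS.COM it ran from 0.485 to 0.791 with 1 array left out and passed without MCF10AT1 CRYBB2 1 (0.0381).

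In MCF10AT1 0 lists (7) passed with an estimated correlation and 0 with fry, and 4 to 11 with 1 array left out (11 without MCF10AT1 CRYBB2 1, 4 without CRYBB2 2). In DCIS.COM 1 list (7) passed with an estimated correlation and 1 with fry, and 5 to 10 with 1 array left out. Between the lines 0 lists (6) passed with an estimated correlation, 15 with fry, and 6 to 10 with 1 array left out (10 without MCF10AT1 control 2). For agreement of the lines, 15 genes moved alike at an unadjusted p under 0.01 (0 at the adjusted p). The pairing by slide entered only as the replicate block, with 1 slide effect common to both lines. Beyond the count of 31 in MCF10AT1 and the calls given with the results, the block changed no other list call. Nor did it change any other count at the adjusted p by over 1.5 times. At an unadjusted p under 0.05 the block gave 2148 genes in MCF10AT1 (1449), 434 in DCIS.COM (234), 1272 averaged (793) and 1008 for the difference (516).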

Other observations

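The families in this part were chosen after the values were seen, and no test of an explanation was run on them. Cross-hybridization between members of a family was not tested, so closely related members may not be separate readings. Between the lines under the control vector, metallothioneins were lower in DCIS.COM: 8 of 9 genes on chromosome 16 passed, among them MT1M (-13.54), MT1F (-3.81) and MT1E (-2.66), and 8 passed under each of the 3 other scalings and without any 1 array. Small proline-rich proteins of the cornified envelope were lower for 8 of 9 genes (median -4.53), also under each scaling. This count was 0 without MCF10AT1 control 1 or DCIS.COM control 2, 1 without MCF10AT1 control 2 and 2 without DCIS.COM control 1. It was 3 with no brightness filter and 3 with 2 and 2.1 averaged and the replicate block. With the CRYBB2 vector in MCF10AT1 all 9 had negative values, none of which passed. Their median was -1.48, but -0.356 without MCF10AT1 CRYBB2 1, the array that stood apart, -0.908 without MCF10AT1 control 1, -2.22 without either array numbered 2.1 and -2.23 with 2 and 2.1 averaged. HOX genes, which set position along the body axis, were higher for 12 of 22 and lower for 1: HOXC4 (3.03) and HOXB6 (2.51) were higher, and HOXC8 (-1.59) was lower. HOXC8 lost its call in the deposited table's scaling, with the replicate block, with 2 and 2.1 averaged, and without any 1 array other than MCF10AT1 CRYBB2 1 and DCIS.COM control 1. HOXC4 lost its call with 2 and 2.1 averaged (adjusted p = 0.0942). With only probes above background on all arrays fewer of the 22 were tested, since some, such as HOXA13 and HOXB4, were dim in 1 line. The count of higher HOX genes was 8 without DCIS.COM control 2, 7 with only probes above background on all arrays and 5 from only the groups compared. HLA genes, counting pseudogenes and an antisense RNA, were higher for 9 of 19, among them HLA-DMB (3.90, at least 4.67-fold) and HLA-B (1.79), with 8 under the normexp scaling and 5 without MCF10AT1 control 1 or DCIS.COM control 2. The probes of HLA-B (31321663 to 31321722) and HLA-C (31321644 to 31321703) overlap on chromosome 6, so the 9 count this stretch as 2 genes. The growth factor carriers IGFBP2 (5.12), IGFBP3 (2.62) and IGFBP4 (2.44, at least 2.63-fold) were the 3 of 6 IGF binding proteins that were higher. IGFBP6 (-1.59, adjusted p = 0.0618) did not pass, although 1 of the 6 passed as lower in some other fits, such as the normexp scaling and the deposited table.

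The aldo-keto reductases AKR1B1, AKR1B10 and AKR1B15, which lie in a row on chromosome 7 (probe starts 134130061, 134225939 and 134262468), had lower values with the CRYBB2 vector in both lines under every scaling. The log2 differences were -0.60, -1.42 and -1.35 in MCF10AT1 and -0.54, -2.81 and -2.87 in DCIS.COM, each with an unadjusted p under 0.01 and none past the adjusted threshold. AKR1B10 and AKR1B15 are close paralogs whose probes were not tested for cross-hybridization. The 2 probes with the firmest calls on chromosome 17 are neighbours: ABCA5 starts at 67243530 and A_33_P3398074 at 67229932, 13598 bases away. Their group means were 11.47 and 7.37 with the MCF10AT1 control vector, against 8.21 and 2.17 with CRYBB2 in MCF10AT1, 9.13 and 3.09 in the DCIS.COM controls and 9.31 and 2.91 with CRYBB2 in DCIS.COM. Of the 9 genes and probes that fell in MCF10AT1, 5 were not well above background on any MCF10AT1 CRYBB2 array and 4 not on any DCIS.COM array.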
